A study of Homo sapiens with 6 samples.

How the data were processed

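RNA-seq was done on total RNA of 6 samples labelled A549, extracted with TRIzol and made into libraries with an mRNA kit, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.36, FastQC 0.11.5, HISAT2 2.2.1.0 and the genome build GRCh38, with no role or order. The read counter, the gene annotation, the strand setting and the gene filter are not given in the sources used here, so overlapping genes, antisense partners and close paralogs could share or lose reads in ways that cannot be traced. A kit that selects poly(A) RNA would retain little 7SK, which has no poly(A) tail; whether this kit does so is not stated.

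For each library the authors deposited a table of whole-number read counts per gene symbol, with no normalization, and a table of FPKM, fragments scaled to gene length and library size. The deposited counts were used for all main results, and the deposited FPKM as a second scale. Each of the 12 tables listed the same 16779 genes, of which 751 had 0 counts in all 6 libraries. Symbols were matched to a RefSeq gene table of the same genome build, 16495 by symbol and 226 by synonym, and 99.7% of the matched genes were protein coding. Coordinates are from that table. GC content was taken from GENCODE transcripts.

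The gene length behind each FPKM was recovered from the ratio of count to FPKM. The lengths came out as whole numbers of bases, within 0.02 bases, for nearly all genes with a value, and differed by at most 0.0678 bases between libraries of a group. Between the groups they differed: of 14582 genes with a length in both, 1019 had the same length and 4716 (32.3%) agreed within 1%. The 2 groups' tables were therefore made with gene lengths that differ. Lengths do not enter the counts, but a gene model also decides which reads are counted for a gene.

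Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr with the group, libraries were scaled by trimmed mean of M values (factors 0.989 to 1.02), and groups were compared with glmQLFit (robust) and glmQLFTest. The p-values are two-sided and Benjamini-Hochberg adjusted over 12929 tested genes, with 0.05 as the threshold. The common biological coefficient of variation was 0.0443. CPM are scaled by the same factors. Total counts of 16018260 to 19357144 per library set the precision; counting intervals are 95% and exact, and they and the floor of 3 counts over a group cover counting error only. No libraries of a group agreed within sampling noise (chi-square per degree of freedom 1.74 to 8.3). On simulated counts with 200 changed genes among 12929, the test called 95.5% of genes changed by a log2 fold change of 2, 97% at 1 and 74.2% at 0.5, and 4.81% of its calls were false. The simulation gave both groups the same spread. In the data the coefficient was 0.056 within the control and 0.0245 within the knockout group, and 85% of tested genes were called. The simulated shares therefore check the method and may not hold for this comparison.

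The design, the alternatives, the rule for named genes and 28 gene lists were fixed before the data were examined. Lists were tested with camera from limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01, two-sided) and adjusted over the 24 lists with at least 5 tested genes. Camera with an estimated correlation and fry, which asks whether the genes of a list move on balance one way, were run beside it. The lists of replication-dependent histone genes, mitochondrially encoded mRNAs and small non-coding RNAs had 0 genes in the tables. Named genes were RN7SK; then, among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, the 12 with the largest positive and the 12 with the largest negative log2 fold change; up to 8 members of the 7SK list; and up to 4 of each other list by smallest p. Named in addition, after their values were seen, were core 7SK and P-TEFb genes, the genes around CDKN2A, the largest changes among genes with at least 20 counts in each library, and list members that went against the rest of their list or that are the best known of it. Some genes that the rule names are not reported here.

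Alternatives were other scalings (DESeq2 size factors, upper quartile, library size), no or a stricter low-count filter, DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 0.1) and log2(FPKM + 1), a replicate block, leaving out each library, a stricter threshold, a fold threshold (glmTreat), and other list tests. Alternatives added after the data were seen were genes with recovered lengths within 1%, leaving out genes at 3 or fewer counts throughout a group, the recovered lengths as an offset, and list tests after removing chromosome medians and a curve on GC content and length. Figures and summaries were made in Python 3.11.15.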

Results

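RNA-seq gene counts were compared between 6 libraries labelled A549, a line derived from a human lung adenocarcinoma. The labels give 3 libraries as wild-type control and 3 as RN7SK knockout. RN7SK encodes 7SK, a small nuclear RNA made by RNA polymerase III that holds the elongation kinase P-TEFb in an inactive complex. The comparison asks which mRNAs differ between cells with and without a working RN7SK gene. Total counts over the 16779 listed genes were 18612303, 19295882 and 19357144 in control replicates 1 to 3, and 18488790, 16666155 and 16018260 in knockout replicates 1 to 3.

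The tables held 0 rows for RN7SK, so the targeted gene could not be used to check the knockout label. A pair of other genes did not go with the cell line named in the labels of the control libraries. CDKN2A (chromosome 9, 21967752 to 21995324, GRCh38) and CDKN2B (chromosome 9, 22002903 to 22009313) encode cell cycle inhibitors, and A549 cells are known to lack both copies of each. In control replicates 1 to 3, CDKN2A had 963, 1005 and 923 counts and CDKN2B had 216, 241 and 238. In the libraries labelled knockout, CDKN2A had 0, 1 and 2 counts and CDKN2B had 0, 1 and 0. The summed ratio of control to knockout was 876.2 for CDKN2A (95% counting interval 299.5 to 4251) and 631.9 for CDKN2B (113 to 24994). These few knockout counts set the fitted log2 fold changes: that of CDKN2A was -9.61, and -9.025 without knockout replicate 1 or -10.505 without replicate 3, and that of CDKN2B was -8.86, and -10.81 without replicate 2. MTAP, a methionine salvage gene beside them, fell from 45.3 ± 1.66 CPM (read counts scaled to library size, mean ± SD, n = 3) to 13.1 ± 1.17 CPM. The groups are therefore named by their labels throughout, and each direction below is that of the libraries labelled knockout against those labelled control.

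Among the genes whose product acts with 7SK, the libraries labelled knockout had more HEXIM1 and HEXIM2 and less of both T-type cyclins. HEXIM1, the inhibitor that binds P-TEFb on 7SK, rose 1.73-fold from 110.4 ± 4.51 to 191 ± 6.95 CPM, and its paralog HEXIM2 rose 4.38-fold from 4.61 ± 0.556 to 20.2 ± 2.19 CPM (n = 3 each). CDK9, the kinase of P-TEFb, rose 1.38-fold, while its cyclin partners CCNT1 and CCNT2 fell by 0.61 and 0.78 on the log2 scale. MEPCE, which caps 7SK, rose 1.42-fold. The recovered lengths of MEPCE, HEXIM1 and CCNT2 were 3754, 4785 and 10883 bases in the control group. In the knockout group they were 3005, 3625 and 8461 bases, and the changes given here are from counts without regard to length. LARP7, which binds the 3' end of 7SK, had 33.6 ± 3.08 CPM in the control and 34.6 ± 2.69 CPM in the knockout group and did not pass the test. The calls of MEPCE, HEXIM1, HEXIM2, CDK9, CCNT1 and CCNT2 had edgeR quasi-likelihood adjusted p between 9.52e-18 and 3.27e-09. As 85% of all tested genes passed this test, passing it does not set these genes apart. LARP7 passed in 3 other settings, all of which use the recovered lengths, 4077 bases in the control and 3242 in the knockout group: log2 fold change 0.4 on log2(FPKM + 0.1) (limma adjusted p = 0.00093), 0.36 on log2(FPKM + 1) (limma adjusted p = 0.00103) and 0.37 with the lengths as an offset in edgeR (adjusted p = 2.57e-05).

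Of the 37 tested genes on the list of 7SK partners and elongation factors, 13 rose, 18 fell and 6 did not pass, and the list as a whole did not pass (median log2 fold change -0.07, camera adjusted p = 0.617). SUPT4H1, a subunit of the pausing factor DSIF, rose by 1.12 ± 0.055 on the log2 scale (fit ± SE). NELFCD, a subunit of the pausing factor NELF, fell by 1.08 ± 0.049, and ELL, an elongation factor, fell by 1.63 ± 0.084. SRSF2, a splicing factor that binds 7SK, fell by 1.08 ± 0.042, and the RNA-binding proteins DDX21 and SYNCRIP fell by 0.73 and 0.71. Adjusted over the list alone, the number of genes that rose and fell was the same as over all genes in every list described here except those for cholesterol synthesis and m6A.

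Genes of the oxidative stress regulator NRF2 rose together. Of 31 tested targets, 30 rose and 1 fell, and the same 30 and 1 were counted adjusted over the list alone (median log2 fold change 1.66, camera adjusted p = 7.91e-10, adjusted p = 0.0733 with an estimated correlation). AKR1B10, an aldo-keto reductase, rose 9.74-fold from 209.5 ± 4.47 to 2040 ± 34.6 CPM (n = 3). The efflux pump gene ABCC2 rose by 2.62 ± 0.044 on the log2 scale. HMOX1, which encodes heme oxygenase 1, was the 1 member that fell (log2 fold change -0.81). AKR1C2 rose by 2.32 ± 0.039, although reads of AKR1C2 and its near-identical paralogs may have been split by the counting.

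Cholesterol and fatty acid synthesis genes were also higher. Of 29 tested, 24 rose and 2 fell, or 24 and 3 adjusted over the list alone (median 0.99, camera adjusted p = 3.44e-05, adjusted p = 0.0733 with an estimated correlation). SCD, which desaturates fatty acids, rose from 739.3 ± 38.9 to 4824 ± 52.8 CPM. The squalene synthesis and oxidation genes FDFT1 and SQLE rose by 1.95 ± 0.046 and 2.17 ± 0.045 on the log2 scale.

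Of 37 genes of the ATF4 and unfolded protein response, 27 rose and 8 fell, also when adjusted over the list alone (median 0.91, camera adjusted p = 0.000787, adjusted p = 0.0839 with an estimated correlation). The 4 members with the smallest p rose: the lipoprotein receptor gene VLDLR by 3.82 ± 0.069, the kinase-like TRIB3 by 3.22 ± 0.05, the serine synthesis gene PSAT1 by 2.53 ± 0.043 and the mTORC1 inhibitor DDIT4 by 2.49 ± 0.044. Among the 8 that fell were HSPA5, HSP90B1, HYOU1 and PDIA4, which encode chaperones of the endoplasmic reticulum and were picked after their values were seen; they had log2 fold changes of -0.29, -0.41, -0.71 and -0.43.

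Interferon-stimulated genes rose in 27 of 34 cases and fell in 4, also when adjusted over the list alone (median 0.86, camera adjusted p = 0.00122, adjusted p = 0.13 with an estimated correlation). The antiviral genes OAS1 and SAMD9 rose by 1.80 ± 0.077 and 1.93 ± 0.1, and IRF9, a subunit of the interferon-activated transcription factor, rose by 1.43 ± 0.075. The RNA sensor gene DDX58 fell by 1.52 ± 0.064. Of 29 p53 targets, 19 rose and 5 fell, also when adjusted over the list alone (median 0.45, camera adjusted p = 0.0167, adjusted p = 0.167 with an estimated correlation). SESN2, PHLDA3 and EDA2R rose by 2.74, 2.02 and 2.80 on the log2 scale, CDKN1A rose by 0.42, and MDM2 did not pass (log2 fold change 0.1).

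Cell cycle genes were lower. Of 41 genes of the G1/S step and DNA replication, 6 rose and 30 fell, also when adjusted over the list alone (median -0.51, camera adjusted p = 0.00122, adjusted p = 0.119 with an estimated correlation). Thymidylate synthase, TYMS, fell from 275.5 ± 6.43 to 108.1 ± 2.86 CPM, the replicative helicase subunit MCM6 fell from 173 ± 4.55 to 73.4 ± 2.25 CPM, and the cyclin gene CCNE2 fell by 2.38 ± 0.095 on the log2 scale. Of 38 genes of G2/M and mitosis, 4 rose and 29 fell, also when adjusted over the list alone (median -0.54, camera adjusted p = 0.00122, adjusted p = 0.286 with an estimated correlation). The spindle checkpoint kinase BUB1 and the anaphase activator CDC20 fell by 1.75 ± 0.053 and 1.46 ± 0.048, while the phosphatase CDC25B rose by 1.80 ± 0.041.

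Splicing regulators fell in 26 of 34 cases and rose in 2, also when adjusted over the list alone (median -0.47, camera adjusted p = 0.00109, adjusted p = 0.378 with an estimated correlation). Besides SRSF2, the splicing factor SRSF3 fell by 1.03 ± 0.044 and RBM5 by 1.32 ± 0.054. With the recovered lengths as an offset, SRSF2 and RBM5 had log2 fold changes of -0.28 and -0.31, and their lengths were 3274 and 6274 bases in the control and 1888 and 3120 in the knockout group. Ribosome biogenesis genes fell in 27 of 40 cases and rose in 7, also when adjusted over the list alone (median -0.52, camera adjusted p = 0.00986, adjusted p = 0.174 with an estimated correlation). NIP7, GNL3 and NOP58 fell by 1.68, 1.14 and 1.12, and RCL1 rose by 1.47. Nuclear genes of oxidative phosphorylation fell in 29 of 43 cases and rose in 10, also when adjusted over the list alone (median -0.4, camera adjusted p = 0.0201, adjusted p = 0.599 with an estimated correlation). SDHA, a subunit of complex II, fell by 1.13 ± 0.046, or to a log2 fold change of -0.51 with the length offset, and the ATP synthase subunit gene ATP5PO fell by 1.03 ± 0.052. Genes of MHC class I antigen presentation fell in 12 of 15 cases and rose in 1, also when adjusted over the list alone (median -0.73, camera adjusted p = 0.00962, adjusted p = 0.167 with an estimated correlation). The peptide-loading genes TAPBP and TAP2 fell by 1.04 ± 0.044 and 1.12 ± 0.052, whereas NLRC5, the transactivator of class I genes, rose by 2.62 ± 0.1. HLA-E had a log2 fold change of -0.8 in counts, but 0.079 on log2(FPKM + 0.1), which did not pass (limma adjusted p = 0.105) and where its recovered lengths of 4820 bases in the control and 2679 in the knockout group enter.

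**Figure D1:**
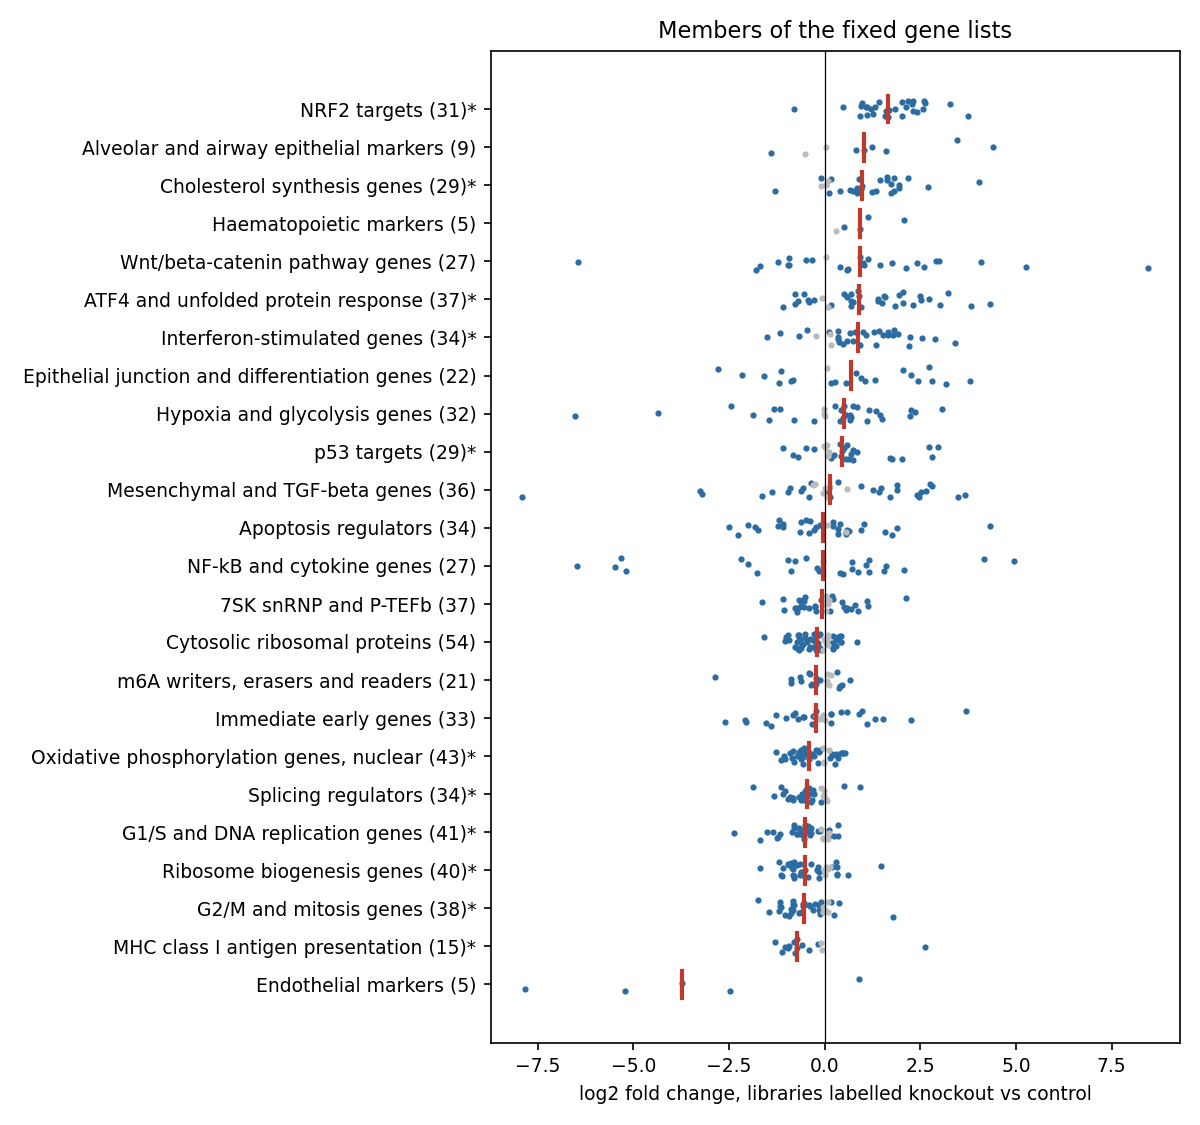
Log2 fold change of each tested gene (points) on the fixed gene lists, libraries labelled knockout against control, with the number of tested genes in parentheses and the list median as a red bar. Blue points passed the edgeR test and grey points did not; an asterisk marks the 11 lists past the camera threshold with the preset correlation, of which NRF2 targets had the highest median (1.66), and none of which passed with an estimated correlation.

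In all, 11 of the 24 testable lists passed camera with its preset correlation, 5 higher and 6 lower, and 0 passed with an estimated correlation, where 7 had an unadjusted p under 0.05. Among genes whose recovered lengths agreed within 1% between the groups, 3 of 20 testable lists passed: G1/S and DNA replication, ATF4 and unfolded protein response, and NRF2 targets. MHC class I and oxidative phosphorylation had under 5 such genes and could not be tested. Lists that lost their call there held far fewer genes, such as 8 of 29 p53 targets and 6 of 34 splicing regulators. Lower power and a dependence on the gene lengths therefore cannot be told apart for them. Camera was also run with chromosome medians and a curve on GC content and length taken out. It then used the remaining fold changes, each divided by the SE of its fit, in place of log2 CPM. Splicing regulators (camera adjusted p = 0.0525), oxidative phosphorylation (0.728) and MHC class I (0.254) were no longer called there. The MHC call was also lost in camera with the recovered lengths as an offset (0.0675) and on signed edgeR statistics (0.0561). That of oxidative phosphorylation was lost among genes with a mean of at least 10 CPM (0.0633). Camera on signed edgeR statistics, with nothing taken out, called epithelial junction genes (0.0119), Wnt pathway genes (0.0112) and endothelial markers (0.00276). Of these, epithelial junction genes (adjusted p = 0.0213) and endothelial markers (0.0004) were also called by camera on the remaining fold changes divided by their SE.

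The other lists did not pass the main list test, though most of their tested members passed theirs. Besides the settings above, epithelial junction genes (adjusted p = 0.0339) and Wnt pathway genes (0.0408) passed camera among genes with a mean of at least 10 CPM. Cytosolic ribosomal protein genes passed with no low-count filter (0.0351) and with the length offset (0.0131), and haematopoietic markers passed without knockout replicate 1 (0.0475) or 2 (0.0387). Inflammatory genes were divided: of 27 NF-kB and cytokine genes, 13 rose and 13 fell (camera adjusted p = 0.935). ICAM1, an adhesion molecule, fell 40-fold from 492.8 ± 29.4 to 12.3 ± 1.17 CPM, and the cytokines IL6 and TNF fell 44.9-fold and 89.2-fold. PTGS2, which makes prostaglandins, rose by 2.07 ± 0.043 on the log2 scale. Of 33 immediate early genes, 12 rose and 17 fell (adjusted p = 0.464 by camera), with DUSP4 and DUSP1, which dephosphorylate MAP kinases, up by 3.71 and 2.26 and EGR1 down (log2 fold change -2.1). Of 27 Wnt pathway genes, 17 rose and 9 fell (camera adjusted p = 0.101). The Wnt feedback inhibitors NKD1 and RNF43 rose 38.6-fold and 17.1-fold, and the ligand WNT5B fell 87-fold.

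Epithelial junction genes rose in 14 of 22 cases and fell in 7 (camera adjusted p = 0.102). E-cadherin, CDH1, rose from 29.2 ± 1.48 to 158.4 ± 4.38 CPM, and the tight junction gene CLDN1 fell from 827.1 ± 13.9 to 118.9 ± 2.65 CPM. Mesenchymal and TGF-beta genes rose in 18 of 36 cases and fell in 11 (camera adjusted p = 0.196): TGFBI and ID2 rose by 2.48 and 3.48, and the activin subunit gene INHBA fell 239.7-fold. Hypoxia and glycolysis genes rose in 20 of 32 cases and fell in 9 (camera adjusted p = 0.102, median 0.5 and mean 0.07). The aldolase gene ALDOA fell from 945.2 ± 21.2 to 10.2 ± 0.804 CPM, and its recovered length was 3609 bases in the control and 2146 in the knockout group. Cytosolic ribosomal protein genes rose in 15 of 54 cases and fell in 32 (camera adjusted p = 0.102), with RPS15 down by a log2 fold change of -1.59. Apoptosis regulators rose in 15 of 34 cases and fell in 17 (camera adjusted p = 0.78), and the inhibitors of apoptosis BIRC2 and BIRC3 fell 3.55-fold and 4.01-fold. The m6A genes rose in 5 of 21 cases and fell in 12, or 11 adjusted over the list alone (camera adjusted p = 0.404), and the m6A reader IGF2BP2 fell by 2.86 ± 0.074.

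Markers of other cell types moved as well. Of 5 tested endothelial markers, 4 fell and 1 rose (median -3.74, camera adjusted p = 0.102). ESAM and ENG fell 37.5-fold and 228.1-fold from 110.1 ± 2.62 and 54.6 ± 3.56 CPM in the control libraries, and ROBO4 had a summed ratio of control to knockout of 14 (95% counting interval 6.6 to 35.7), with a fitted log2 fold change of -3.74, or -4.36 without knockout replicate 2. Of 5 haematopoietic markers, 4 rose (adjusted p = 0.0618 by camera), among them CD14 from 1.69 ± 0.06 to 7.1 ± 0.786 CPM. CD8A, from 0.686 to 1.31 CPM, lost its call without knockout replicate 1 (edgeR adjusted p = 0.0628) and under DESeq2 (adjusted p = 0.0558), over a range of 0.000451 to 0.0628 in all alternatives. Of 9 alveolar and airway markers, 6 rose and 1 fell (adjusted p = 0.196 by camera). The mucins MUC5AC and MUC5B rose 10.9-fold and 21.2-fold, and CAV1 fell by 1.40 ± 0.04. Of the 4 tested fibroblast markers, TWIST2, COL1A1 and COL5A2 rose and FBN1 fell, and 4 genes were too few for a list test.

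Over all genes, the libraries labelled knockout and control differed in most of what was measured. Of 12929 tested genes, 5428 rose and 5564 fell, which is 85% of them, and 2523 rose and 1822 fell at least 2-fold. SUSD2, a membrane protein gene (chromosome 22, 24181487 to 24189106), rose 95.2-fold from 2.99 ± 0.226 to 285.9 ± 6.99 CPM. The receptor phosphatase PTPRD rose 125.8-fold, SAMD11 57-fold, the cadherin FAT3 57.6-fold, the transcription factor gene ATOH8 52.1-fold and keratin KRT4 43.3-fold. GGT5, DPYSL5, HS6ST2 and SP9 rose by 5.58, 5.43, 5.33 and 5.27 on the log2 scale, and SP9 by 6.12 without control replicate 3. These sizes depend on the scale: on log2(FPKM + 0.1), where the added 0.1 shrinks the change of low genes, FAT3 had a log2 fold change of 2.48 (5.85 in counts), PTPRD 5.67 (6.98), ATOH8 4.44 (5.7), KRT4 4.82 (5.44), SAMD11 5.08 (5.83), DPYSL5 4.34, HS6ST2 4.25 and SP9 4.03. TENM4, an adhesion gene with 0 counts in the 3 control libraries, was at least 425.3-fold higher, taking 3 counts over the group as the floor.

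Of the 12 genes with the largest fall, 10 were at 0 counts in the 3 libraries labelled knockout, so their folds are lower bounds from the same floor. CHTF8, a subunit of a clamp loader complex (chromosome 16, 69118010 to 69132588), had 2591, 2750 and 2808 counts in the control libraries and was at least 2469.7-fold lower. FKBP2 was at least 957.4-fold lower, UTP14C at least 405.8-fold, ZNF100 at least 313.7-fold, CYYR1 at least 310.9-fold, B3GALNT1 at least 310.6-fold, ZNF90 at least 256.7-fold, ZNF93 at least 255.8-fold, ZNF700 at least 237-fold and the chemokine gene CXCL6 at least 200.3-fold. The spans of CHTF8, FKBP2, UTP14C and ZNF700 overlap other protein-coding genes, so their counts depend on how shared reads were assigned. MYL9, a myosin light chain gene, had a ratio of 3249 (95% counting interval 1112 to 15758) that rests on knockout replicate 1, since the knockout counts were 3, 0 and 0; the fitted log2 fold change of -11.5 became -14.73 without that library. It had recovered lengths of 1197 bases in the control and 2786 in the knockout group. The metallothionein gene MT1E fell 1345-fold from 374.3 ± 19.2 to 0.271 ± 0.026 CPM, with recovered lengths of 848 and 398 bases and with close paralogs. Among genes counted at least 20 times in each library, CPLX2, a regulator of vesicle fusion (chromosome 5, 175796533 to 175884021), rose from 121.2 ± 2.78 to 2829 ± 28.1 CPM, PAX8, a lineage transcription factor, fell from 120.6 ± 6.82 to 1.66 ± 0.162 CPM, and the transporter SLCO4A1 from 628.5 ± 57.7 to 11.1 ± 0.705 CPM.

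**Figure D2:**
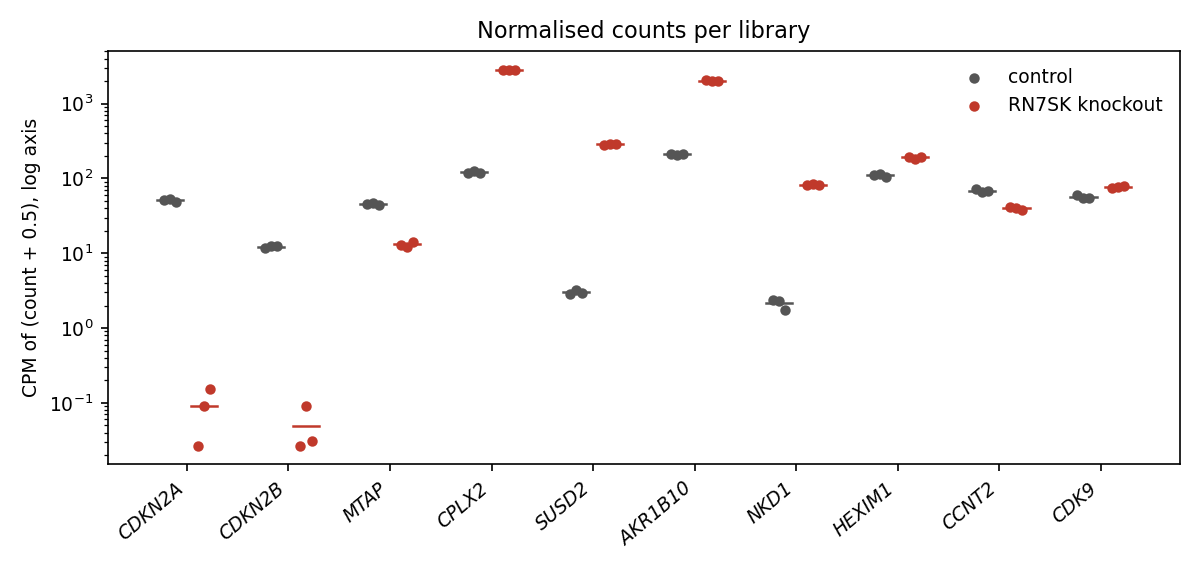
CPM of (count + 0.5) on a log axis for 10 genes in each of the 6 libraries (points; the short lines are group means). CDKN2A, CDKN2B, MTAP and CCNT2 were lower in the libraries labelled knockout and the other 6 genes were higher, with no overlap between the groups in any of the 10.

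Fold changes also differed between chromosomes, a comparison added after the data were seen. Genes of chromosomes 18 and 21 had median log2 fold changes of -0.62 and -0.63 (171 and 112 genes), and genes of chromosomes 6 and 1 had -0.33 and -0.27. The medians of chromosomes 10, 8, 17, 9 and 15 were 0.37, 0.36, 0.25, 0.25 and 0.22. These 9 of 23 chromosomes passed camera with the preset correlation, and chromosomes 1, 8, 10 and 21 also passed with an estimated correlation.

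**Figure D3:**
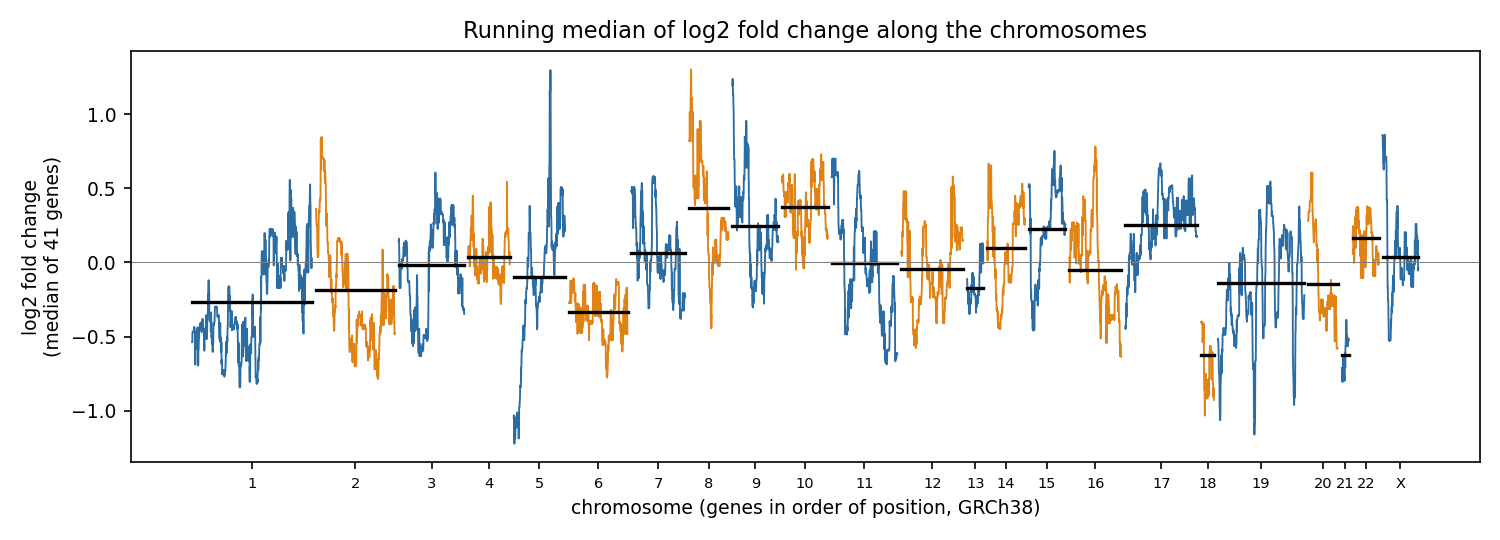
Running median over 41 genes of the log2 fold change (libraries labelled knockout against control) along the chromosomes, with genes in order of position and adjacent chromosomes in alternating colours; black bars are chromosome medians. The medians run from -0.63 on chromosome 21 to 0.37 on chromosome 10.

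With the recovered lengths as an offset, 7 other genes named here also moved by more than 1.5 times: the log2 fold changes became 3.01 for VLDLR, -5.79 for ALDOA, -4.54 for IL6, -1.35 for BIRC3, 4.47 for SP9, -9.32 for MT1E and -12.66 for MYL9. On log2(FPKM + 0.1) they were 2.97, -5.73, -4.45, -1.31, 4.03, -9.12 and -10.37. On that scale NKD1 (4.52), INHBA (-6.41), ENG (-6.48), ROBO4 (-2.13), SRSF2 (-0.26), RBM5 (-0.28), SDHA (-0.48), CDKN2A (-6.64) and CDKN2B (-4.88) moved by more than 1.5 times too, as did the genes given as bounds, and log2(FPKM + 1) shrank further ones, such as SUSD2 (5.56).

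The changed genes were called with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The 3 libraries of each group did not overlap in 11066 of the tested genes, where chance gives 10% of genes. Within groups the correlation of log2 CPM across genes was 0.994 to 0.996, and between groups 0.829 to 0.835; genes are not independent replicates. Group and any difference in the cells or their handling fall together in these 6 libraries, so the comparison does not separate them, and the gene lengths behind the tables differ with the group too. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.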

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

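The tests of RN7SK itself, of gene models among the genes present in 1 group alone, of CDKN2A and CDKN2B, and of genes 50 places apart after removal of chromosome medians were chosen after their results had been seen; the other tests of explanations were chosen before.

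One signal lay in data that the comparison of counts does not use, the gene lengths behind the FPKM. They differed by more than 1% between the control and the knockout group for 67.7% of genes with a length in both, while within a group they agreed to a fraction of a base.

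The first pattern is breadth: 85% of tested genes differed between the libraries labelled knockout and control. Different gene models as the whole cause are argued against, since genes with the identical recovered length were called about as often (84.4%, 95% exact interval 81.7 to 86.8, n = 794). Bias by GC content and gene length is a separate explanation. A curve on GC content and the mean length of both groups took 2.5% of the variance of log2 fold changes, which argues against that bias as the whole cause. The real grouping called 10992 genes by edgeR and the highest of the other splits of the 6 libraries 0 (at most 4 at an unadjusted p under 0.05), so 1 of 10 splits called as many, and with 10 splits the share cannot go under 0.1. Each other split also puts libraries of both groups on each side. The group difference then widens its spread, so few calls were fixed in advance and the splits cannot decide about chance. RN7SK has 0 rows, so its loss could not be read, and it stays open and untested. Handling that differs with the group stays open and untested too. Cells that differ with the group were not tested against this breadth. The counts of CDKN2A and CDKN2B given below do bear on the cells, and argue against control libraries of A549 cells alone.

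The second pattern is 77 genes at 3 or fewer counts throughout one group and at 100 or more in each library of the other, 68 of them low in the libraries labelled knockout. Of the 59 with a length in both groups, 11.9% had lengths 1.5 times or more apart (95% exact interval 4.91 to 22.9), against 8.58% of all genes. Of the 77, 22.1% overlapped another protein-coding gene, against 24.2% of other tested genes. Neither a length difference of that size nor such an overlap therefore accounts for the set as a whole. Whether gene models or the counting took reads from these genes without either sign, as between paralogs, was not tested. For the 18 genes at 0 throughout a group no length could be recovered there; 27.8% of them overlapped another gene (95% exact interval 9.69 to 53.5), and for these, CHTF8 and FKBP2 among them, a gene model without the gene cannot be told apart from loss of its RNA. A candidate explanation for the rest is cell populations that do not share a genome or lineage: CDKN2A and CDKN2B, which A549 cells are known to lack, had no control count below 216 and no knockout count above 2. Cells that lack CDKN2A and CDKN2B would give no such counts, so the control counts of both genes argue against control libraries of A549 cells alone. In A549 cells, neither a clone that lost genes nor an effect of RN7SK loss would give them. For the other genes of the set, 3 explanations stay open. These are a knockout clone of the control cells that lost them, a mislabelled or mixed control culture, and an effect of RN7SK loss.

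The third pattern is that median log2 fold changes differed between chromosomes, from -0.63 on chromosome 21 and -0.62 on chromosome 18 to 0.37 on chromosome 10. By camera 9 of 23 chromosomes passed (5 higher, 4 lower), and 4 with an estimated correlation. Taking out GC content and length left 107.3% of the spread of the medians, which argues against that bias as the cause. Genes with lengths within 1% had 118.5% of it, but they are fewer, and medians over fewer genes vary more. Among them the 9 chromosomes kept their direction, from -0.78 on chromosome 21 to 0.45 on chromosome 10. That argues against different gene models as the whole cause. After the correction for GC content and length, genes 50 places apart on a chromosome correlated (Spearman 0.0684 across genes, against at most 0.0208 in 100 random orders), which differing medians alone would give. With chromosome medians taken out and orders drawn within chromosomes, a weak correlation was left (0.0255 against at most 0.0187). Copy number that differs in segments is a hypothesis for it. Clusters of related genes that move together, such as the zinc finger genes of chromosome 19, would also give it and were not taken out. Copy number was not measured, whole-chromosome differences in it cannot be told apart from other chromosome-wide shifts, and regional regulation after loss of RN7SK stays open, as untested.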

How the results depend on the processing

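Tests on genes with lengths within 1%, with a length offset, without genes near 0 in a group and after removing chromosome medians were chosen after seeing the data. The number of changed genes (10992) lay within 1.5 times of itself in each alternative but 2: glmTreat against a log2 fold change of 0.5 called 6663 (3470 higher, 3193 lower), and genes with lengths within 1% gave 3451 (1719 higher, 1732 lower, 1430 at least 2-fold), as 4057 genes were tested. Leaving out 1 library gave 10697 to 11132. The balance of directions depended on the scaling. More genes were higher than lower with upper-quartile factors (5900 and 5033) and with the length offset (5731 and 5223). With limma-voom, as in the main test, more were lower (5433 higher and 5546 lower). The 4345 genes changed at least 2-fold became 2347 with a mean of 10 CPM or more, where 9756 genes were tested, and 2628 on log2(FPKM + 1), which shrinks low genes. Of calls shared with the main test, 330 of 10300 on log2(FPKM + 0.1), 332 of 10290 on log2(FPKM + 1) and 323 of 10389 with the length offset had the opposite direction, and 0 in each other alternative where directions were compared. The 11 lists past camera became 0 with an estimated correlation and 23 with fry, which asks another question. For lengths within 1% they became 3 of 20. There MHC class I and oxidative phosphorylation could not be tested, and the lists that lost their call held fewer genes. HLA-E reversed to 0.079 on log2(FPKM + 0.1), 0.077 on log2(FPKM + 1) and 0.051 with the length offset, none of which passed (adjusted p 0.105, 0.105 and 0.313; over all its alternatives 1.05e-78 to 0.313); these settings take up the recovered lengths. The replicate numbers did not pair the libraries (correlations of same-numbered deviations 0.018, -0.025 and -0.008), and the replicate block called 10910 genes, 10886 of them shared. Restricting to genes listed in all tables was not run, since all tables list the same genes. Of the values of named genes, 2687 kept direction and call, 3 gained a call, 2 lost it and 3 reversed; of single lists, 403 kept their call, 23 gained and 23 lost it. The depth leaves folds of genes at 0 as lower bounds.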

Other observations

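The tests below were chosen after the data were seen.

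Zinc finger genes of chromosome 19, which encode mostly KRAB repressors of transposable elements, were lower in the libraries labelled knockout. Of 222 tested genes named ZNF on chromosome 19, 34 rose and 162 fell, with a median log2 fold change of -1.02. The family was picked because it was seen among the 77 genes near 0 in one group, so it was counted without those: of the other 202, 59 were at least 4-fold lower, 29.2%, against 3.99% of the other tested genes (Fisher's exact test p = 8.25e-33, two-sided, across genes, which are not independent replicates). That p-value still follows a choice made on these data. Of 229 ZNF genes on other chromosomes, 88 rose and 106 fell, and 3.49% were at least 4-fold lower. ZNF320 had 1778, 1827 and 1886 counts in the control libraries and 2, 2 and 0 in those labelled knockout, and ZNF83 had 786, 831 and 819 against 1, 0 and 1. Reads of these paralogs could be split by the counting; of the 77 genes near 0 in one group, 20 were of this family. Of these 20, 6 overlapped another protein-coding gene, ZNF83 among them, against 22.1% of the 77.

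Single genes near 0 in one group, picked after their values were seen, follow. HOXA9, whose span overlaps another protein-coding gene, had 135, 167 and 154 counts in the control libraries and 1, 0 and 3 in those labelled knockout, and HOXD9 157, 187 and 171 against 0, 2 and 1. The adhesion gene CDH13 had 284, 275 and 351 against 1, 1 and 0, and the p53 family gene TP73 251, 227 and 263 against 0, 2 and 3. In the other direction, LGR5, which encodes a receptor for R-spondins, had 0, 1 and 0 counts in the control libraries and 153, 152 and 141 in those labelled knockout. Along the chromosomes, the lowest running median of 41 genes was -1.22 on chromosome 5 near position 7850859, and the highest was 1.30 on chromosome 8 near 17576433.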
